A study of Rattus norvegicus with 60 samples.

How the data were processed

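RNA was sequenced from the lungs of male Fischer rats that had breathed filtered air or multi-walled carbon nanotubes (MWCNT) in whole-body chambers. Per the labels, exposure lasted 6 hours a day for 3 days, and lungs were taken 1 day after it ended. There were 5 exposure sets, one for each cumulative MWCNT dose of 180, 90, 45, 22.5 and 11.25 mg/m3, and each set had 6 exposed rats and its own 6 rats in air. The sets are called 180, 090, 045, 022 and 011 here. Total RNA from a piece of lung went into a stranded mRNA library with 12 cycles of PCR.

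The deposited table holds raw counts per gene symbol for 60 libraries, in 30045 rows. The submitters' notes name bcl2fastq 2.19, Trimmomatic 0.35, HISAT2 2.1.0, Cufflinks with no version, SAMtools 1.8 and HTSeq 0.11.2. The genome build and gene annotation are not given in the sources used here, so genes are identified by the symbols in the table and no coordinates are reported. A spreadsheet date stood in place of the symbol in 27 rows, and 2 symbols occurred more than once. A reference gene table was used only to check names, and 19073 symbols matched it.

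The labels mark 7 libraries as outliers in the submitters' own work, namely air_045 replicates 3, 5 and 6, MWCNT_090 replicates 5 and 6, MWCNT_011 replicate 2 and MWCNT_180 replicate 1. The other 53 libraries were analysed. This left 3 libraries in air_045, 4 in MWCNT_090, 5 in MWCNT_011 and in MWCNT_180, and 6 in each other group. The sample choice, the tests, the gene lists, the rule for naming genes and most of the alternative settings were fixed from the labels before the data were examined.

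Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with enough counts in at least the smallest group were kept by filterByExpr with a minimum count of 10, which left 15995 genes holding 99.932% of the counts and removed 14050. Libraries were scaled by TMM. A single robust quasi-likelihood model with the 10 set-by-treatment groups was fitted, and its common biological coefficient of variation was 0.107. Each set's exposed rats were compared only with the air rats of the same set, by edgeR's two-sided quasi-likelihood F-test. Further contrasts of the same model tested a linear change of the MWCNT effect per doubling of dose, any difference of the effect among the 5 sets, and any difference among the 5 air groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Levels are counts scaled to a library total of 1000000 (CPM) with the standard deviation (SD) over rats.

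A total of 33 gene lists for cell types, pathways and stress responses was tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated from the data. Camera p-values were adjusted over the 33 lists within each comparison. Counts of called list members are given over all genes tested and adjusted over the list alone. Genes were named by a rule. It took the 12 largest rises and the 12 largest falls in set 180 among called genes with a mean of at least 1 CPM whose exposed libraries all lay on one side of the air mean. It took the first 5 each way in each other set by the same conditions, and for the dose slope without the condition on single libraries. It also took the 5 smallest p-values for the difference between sets, up to 4 members of each list, and a fixed group of inflammation and lung genes. Symbols that carry no gene name were passed over, and there were 10 of them in set 180, 10 in 090, 26 in 045, 24 in 022 and 0 in 011. Il6 and Tnf were in the fixed group but were removed by the filter on low counts.

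Total counts of the analysed libraries ran from 8.1 to 16.2 in units of 1000000, with a median of 11.2 and a ratio of largest to smallest of 2. The method was tested on simulated data built from the mean profile and the fitted spread of each gene, with 40 genes changed at each size. In set 180 the test called 70% of 1.5-fold rises, 92.5% of 2-fold rises and 100% of 4-fold rises, with 7 false calls among 15853 genes. In set 045, with 3 air libraries, it called 47.5%, 90% and 100% of these, with 5 false calls. Of 1.5-fold falls it called 82.5% in set 180 and 77.5% in set 045. With no change put in, 0 genes were called in set 022 by the same edgeR test. The simulation used the same spread of a gene in all groups, so it does not carry the spread of set 022 alone. No pair of libraries within a group was a duplicate, since the smallest chi-square per degree of freedom was 2.52. Reads were counted without molecular identifiers, so counting error alone is a lower limit on the uncertainty.

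The alternative settings fixed in advance were all 60 libraries, DESeq2's size factors in edgeR, no filter, a stricter filter of 1 CPM in 10 libraries, DESeq2 1.42.0, limma voom with quality weights, each set fitted alone, all air rats as a single control, a linear dose scale, and leaving out each library and each set in turn. Alternatives chosen after seeing the data were 57 libraries (the 60 without 3 that held a liver profile), subtraction of a liver trace from each library, and removal of the 5 libraries with the highest trace. Labels were also shuffled within sets, or among all air libraries for the difference between air groups, with 100 splits for each comparison or all 84 in set 045. For set comparisons the shuffled fits used the libraries of that set alone. Where a group of a set had no counts of a gene, a fold was bounded with a floor of 3 counts over the group.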

Results

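The data are lung mRNA profiles of rats killed 1 day after inhaling multi-walled carbon nanotubes (MWCNT), fibrous carbon particles, or filtered air. Each of the 5 cumulative doses, 11.25, 22.5, 45, 90 and 180 mg/m3, had its own 6 exposed rats and 6 rats in air. After the 7 libraries with an outlier label were set aside, 53 libraries remained. Mean depth, in units of 1000000 counts, was 11.1 in air_180 (n = 6) and 9.39 in MWCNT_180 (n = 5). It was 11 in air_090 (n = 6) and 11.7 in MWCNT_090 (n = 4), 12.3 in air_045 (n = 3) and 13.6 in MWCNT_045 (n = 6). The means were 11.9 in air_022 and 12.1 in MWCNT_022 (n = 6 each), and 11 in air_011 (n = 6) and 11.3 in MWCNT_011 (n = 5). Because each dose was a separate run, dose and run differ together between sets. A set's own air group removes the baseline of its run, but the size of the effect at a dose is not separated from the run, nor are the slope over doses and the difference between doses.

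Among the libraries with an outlier label, 3 held a liver profile. Genes of a list of liver markers, such as albumin and other plasma proteins, took 24.3% of the counts in air_045 replicate 5, 26.2% in MWCNT_090 replicate 5 and 27.9% in MWCNT_090 replicate 6. The highest share in any analysed library was 0.0564%.

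**Figure D1:**
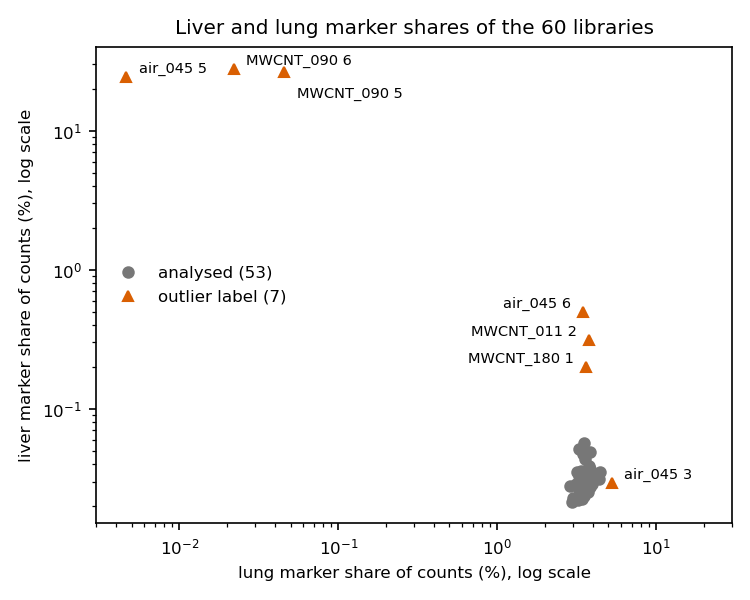
Share of counts in liver marker genes (vertical, percent, log scale) against the share in lung marker genes (horizontal, percent, log scale), 1 point per library, 60 libraries. The 3 libraries at the upper left have liver shares from 24.3 to 27.9%, and the 53 analysed libraries lie at 0.0564% or below.

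The highest dose against its air group asks which genes responded to 180 mg/m3. Among the genes that rose were chemokines that draw monocytes and T cells. Ccl2 went from 2.57 ± 1.46 CPM (SD, n = 6) in air to 29.9 ± 6.05 (n = 5), an 11.4-fold rise (log2 fold change 3.51 ± 0.25 SE, adjusted p = 1.5e-15). Spp1, which encodes the secreted phosphoprotein osteopontin, went from 4.42 ± 2.33 CPM to 105 ± 18.3 (4.58 ± 0.41, adjusted p = 4.6e-12). The proliferation marker Mki67 rose from 14.5 ± 2.49 CPM to 45.8 ± 3.79 (1.66 ± 0.10, adjusted p = 1.3e-17). Scgb1a1, the main secretory protein of club cells, fell from 5982 ± 1034 CPM to 3505 ± 297 (-0.77 ± 0.14, adjusted p = 2.3e-05). In each of these 4 genes all 5 exposed rats lay on one side of the air mean, which the naming rule required of Ccl2 and Spp1.

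The other large rises in set 180 also held in 5 of 5 exposed rats, as the naming rule required. They were the chemokines Ccl22 (log2 fold change 3.65 ± 0.20) and Ccl7 (3.34 ± 0.32), the acute phase protein Orm1 (3.46 ± 0.51), and Retnla, a resistin-like protein of alternatively activated macrophages (3.35 ± 0.30). The anion exchanger Slc26a4, also called pendrin (3.34 ± 0.29), the transcription factor Foxn4 (3.42 ± 0.31), Ccno (3.17 ± 0.14), which is needed for centriole amplification in multiciliated cells, the serine protease Prss30 (3.64 ± 0.31), the matrix protein Tnn (3.48 ± 0.37) and Saal1 (3.20 ± 0.24) completed the group. Their adjusted p-values ran from 6.6e-23 for Ccno to 5.6e-07 for Orm1. The MWCNT_180 libraries had a trace of liver transcripts that corresponds to 8.68% of the Orm1 level and 3.93% of the Cidec level in that group. The air_180 libraries had such a trace too. In percent of a liver profile it ran from 0.00297 to 0.117 in air_180 and from 0.0107 to 0.0712 in MWCNT_180.

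Among the largest falls in set 180 were Serpinb10, a serine protease inhibitor of leukocytes (-2.05 ± 0.13, adjusted p = 2.5e-17), and Alox15, the arachidonate lipoxygenase of eosinophils and macrophages, from 32.9 ± 3.4 CPM to 8.69 ± 1.21 (-1.93 ± 0.14, adjusted p = 7.5e-16). Fat and energy genes were Cidec, a lipid droplet protein (-1.92 ± 0.27), the peroxisomal transporter Abcd2 (-1.40 ± 0.13) and the mitochondrial uncoupling protein Ucp3 (-1.35 ± 0.16). Pla2g2d, a secreted phospholipase (-1.69 ± 0.14), Dlk1 (-1.83 ± 0.33), the CD30 receptor Tnfrsf8 (-1.48 ± 0.20), Hmcn2 (-1.35 ± 0.29) and the potassium channel subunit Kcnmb2 (-1.33 ± 0.25) fell too. The cytochromes P450 Cyp2a3 (-2.63 ± 0.71, adjusted p = 0.0046) and Cyp2f4 (-1.57 ± 0.38, adjusted p = 0.0018) varied most between rats. With set 180 fitted alone, adjusted p was 0.067 for Cyp2a3 and 0.054 for Cyp2f4, and with limma voom it was 0.051 for Cyp2a3.

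**Figure D2:**
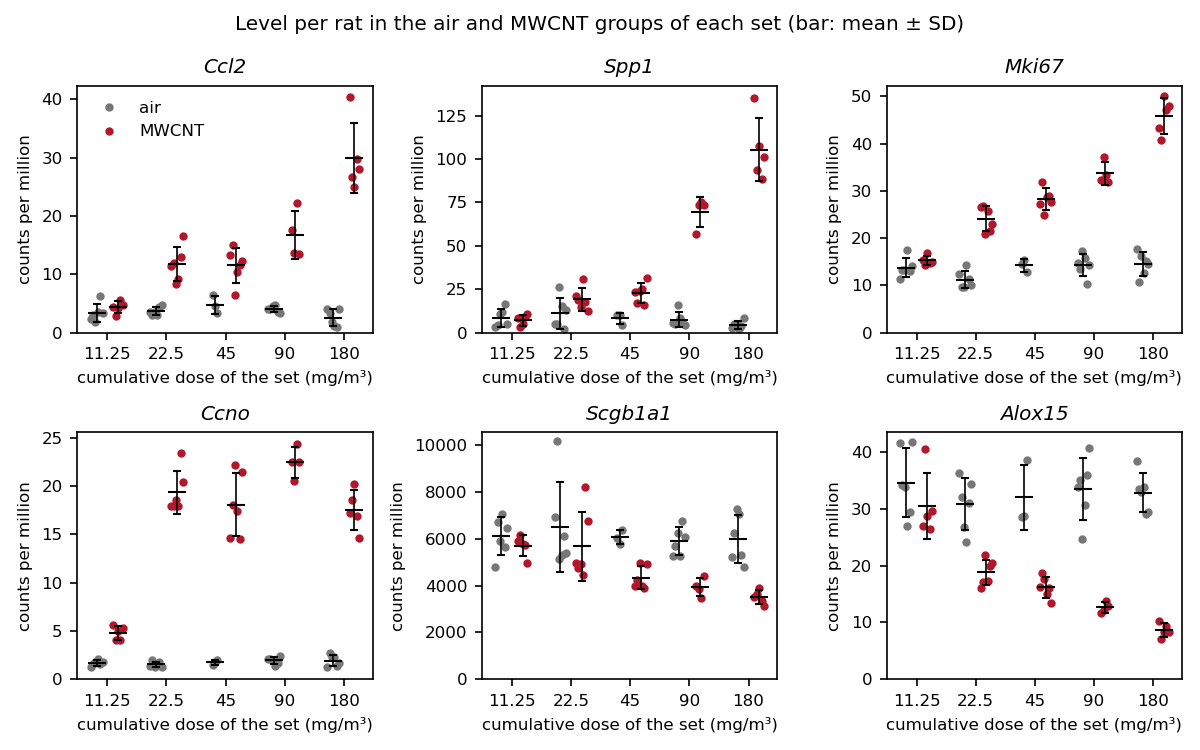
Level of Ccl2, Spp1, Mki67, Ccno, Scgb1a1 and Alox15 (vertical, CPM) in each rat by the cumulative dose of its set (horizontal, mg/m3), with grey points for air, red points for MWCNT and bars for the mean ± SD. Ccno rises at each dose, from 1.69 to 4.79 CPM at 11.25 mg/m3 and from 1.92 to 17.5 CPM at 180 mg/m3.

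In set 180, 3660 of the 15995 genes tested were called, 1921 of them higher and 1739 lower. More than 2-fold changes were 364 up and 71 down. The median log2 fold change over all genes tested was -0.00657.

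Inflammatory genes moved as groups in set 180. Of 29 chemokines, 18 rose, 3 fell and 8 did not pass; the counts adjusted over the list alone were 19 and 3, and the median log2 fold change was 0.72. Besides those named, Cxcl6 (3.16 ± 0.35) and Cxcl1 (1.94 ± 0.22), which attract neutrophils, and Ccl17 (2.74 ± 0.27) rose, while Cxcl14 (-0.59 ± 0.13), Ccl5 (-0.45 ± 0.15) and Ccl6 (-0.31 ± 0.11) fell. Of 12 cytokines, 8 rose and 1 fell (9 and 2 adjusted over the list alone), among them Il1b (1.01 ± 0.16), its receptor antagonist Il1rn (1.02 ± 0.09) and the macrophage growth factor Csf1 (0.79 ± 0.08). The single fall was in the alarmin Il33 (-0.26 ± 0.05, adjusted p = 5.7e-05). Of 19 acute phase and innate defence genes, 15 rose (16 adjusted over the list alone), with a median of 0.71, including the acidic chitinase Chia (2.26 ± 0.12), the iron-binding lipocalin Lcn2 (2.57 ± 0.23), Chi3l1 (1.81 ± 0.11) and complement C3 (1.57 ± 0.11). Camera adjusted p was 3.16e-17 for chemokines, 6.44e-06 for cytokines and 3.28e-32 for the acute phase list, and 0.000234, 0.0061 and 4.63e-07 with an estimated correlation.

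Myeloid cell lists also shifted in set 180. Of 15 monocyte and dendritic cell markers, 9 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.61. Among those that rose were the markers of cross-presenting dendritic cells Clec9a (1.15 ± 0.11) and Xcr1 (1.16 ± 0.15) and their transcription factor Irf8 (0.72 ± 0.07). Of 10 MHC class II genes, 7 rose (8 adjusted over the list alone), including the class II transactivator Ciita (0.62 ± 0.08) and RT1-Bb (0.46 ± 0.07). Camera adjusted p was 7e-07 and 3.31e-05, and 0.000488 and 0.0408 with an estimated correlation. Of 15 neutrophil markers, 7 rose and 1 fell (7 and 2 adjusted over the list alone), led by the decoy receptor gene Il1r2, from 2.73 ± 0.644 to 10.9 ± 2.36 CPM, and S100a9 (1.06 ± 0.16). Of 17 macrophage markers, 7 rose, such as the complement gene C1qb (0.82 ± 0.10) and the integrin Itgax (0.85 ± 0.10), and 3 fell, such as the lipid exporter Abcg1 (-0.60 ± 0.10), the same counts as adjusted over the list alone. Of 19 genes of lipid-associated and scar macrophages, 10 rose and 3 fell (11 and 3 adjusted over the list alone), with the elastase Mmp12 (2.49 ± 0.26), Ctsk (1.56 ± 0.23) and the cystine transporter Slc7a11 (1.98 ± 0.22) beside Spp1. Camera adjusted p for these last lists was 0.0021, 0.034 and 3.83e-08, and adjusted p = 0.162, 0.495 and 0.11 with an estimated correlation.

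Cell division and cholesterol synthesis genes rose almost as whole lists in set 180. Of 33 cell cycle genes, 32 rose (33 adjusted over the list alone), with a median of 1.36, among them the replication helicase subunits Mcm5 (1.71 ± 0.11) and Mcm6 (1.04 ± 0.07), thymidine kinase Tk1 (1.54 ± 0.11) and Ccnb1 (2.07 ± 0.16). All 19 cholesterol synthesis genes rose, the same count as adjusted over the list alone, with a median of 0.71, including Idi1 (1.11 ± 0.10), Hmgcs1 (0.96 ± 0.10), Cyp51 (0.91 ± 0.08) and Fdft1 (0.71 ± 0.07). Camera adjusted p was 1.45e-79 and 4.56e-29, and 3.19e-10 and 0.000234 with an estimated correlation.

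Structural cell lists of the lung moved in different directions in set 180. Of 18 endothelial genes, 13 fell and 0 rose by edgeR (14 and 0 adjusted over the list alone), with a median of -0.31, such as the receptors Tie1 (-0.31 ± 0.05) and Tek (-0.32 ± 0.05) and the transcription factor Sox17 (-0.45 ± 0.07). Of 15 genes of alveolar type 1 (AT1) cells, the flat gas-exchange cells, 7 fell (9 down and 1 up adjusted over the list alone), such as Cav1 (-0.43 ± 0.06) and Vegfa (-0.36 ± 0.06). Camera adjusted p was 6.2e-09 and 0.000234, and 0.00454 and 0.0174 with an estimated correlation. Of 15 genes of surfactant-making alveolar type 2 (AT2) cells, 8 rose (9 adjusted over the list alone), including the surfactant proteins Sftpa1 (0.61 ± 0.10) and Sftpd (0.55 ± 0.10) and the mucin Muc1 (0.64 ± 0.09). Of 19 ciliated cell genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone), with Mcidas (2.40 ± 0.30), a switch for multiciliated cell formation, Dnai2 (0.85 ± 0.15) and Foxj1 (0.62 ± 0.13) up and Tppp3 (-0.55 ± 0.10) down. Camera adjusted p was 0.000534 for AT2 genes and 0.00102 for ciliated cell genes, and adjusted p = 0.396 and 0.483 with an estimated correlation. Of 17 club and goblet genes, 4 rose and 5 fell (6 and 5 adjusted over the list alone), with the mucin Muc5ac (2.95 ± 0.62) and the secreted defence protein Bpifb1 (2.45 ± 0.51) up and Cyp4b1 (-0.98 ± 0.05) down, and camera adjusted p was 0.225.

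Several stress lists also passed in set 180. Of 20 NRF2 and oxidative stress genes, 7 rose, led by metallothionein Mt2A (2.03 ± 0.25), Slc7a11 (1.98 ± 0.22) and the mitochondrial superoxide dismutase Sod2 (1.40 ± 0.08), with Hmox1 at 0.59 ± 0.12 (adjusted p = 2.8e-04). Of 17 immediate early genes, 4 rose, led by Nr4a3 (2.32 ± 0.16). Of 19 ER and heat stress genes, 7 rose, such as the chaperone Hspa5 (0.38 ± 0.09), and of 20 lysosome and proton pump genes, 6 rose (7 adjusted over the list alone), such as Atp6v0d2 (1.61 ± 0.24). The counts adjusted over the list alone were the same for the other 3 lists. Camera adjusted p for NRF2, immediate early, ER and lysosome lists was 5.61e-05, 0.013, 0.034 and 0.0113, and adjusted p = 0.339, 0.495, 0.495 and 0.495 with an estimated correlation. Of 5 adipose tissue genes, 3 fell, the same count as adjusted over the list alone, Cidec, the adipsin gene Cfd (-0.67 ± 0.14) and the lipase Lipe (-0.28 ± 0.08), with camera adjusted p = 0.0113, and 0.0288 with an estimated correlation.

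The remaining lists did not pass the camera test in set 180. Of 32 interferon response genes, 4 rose (3 adjusted over the list alone), including Cxcl10 (1.82 ± 0.29), and of 10 inflammasome genes, 3 rose, including Nlrp3 (0.48 ± 0.10). Of 24 T and NK cell markers, 2 rose, such as Ctla4 (1.54 ± 0.32), and 5 fell, such as Cd8a (-0.44 ± 0.12, with adjusted p = 0.052 against all air rats as a single control). Of 15 B and plasma cell markers, 2 rose, Irf4 (0.85 ± 0.10) and Fcrla (0.61 ± 0.14), and of 9 eosinophil and mast cell markers, 2 rose, with Ccr3 at 1.07 ± 0.19, and 1 fell, Alox15. Of 25 fibroblast, matrix and remodelling genes, 4 rose and 5 fell (5 and 5 adjusted over the list alone), with Timp1 (0.86 ± 0.11) up and the elastin gene Eln (-0.60 ± 0.07) down. Of 12 glucocorticoid target genes, 3 rose (3 up and 2 down adjusted over the list alone), Mt1a, Mt2A and Lcn2. Of 12 cardiac and skeletal muscle genes, 2 rose, with the muscle actin Acta1 at 1.67 ± 0.33, although the median of the list was -0.72. In the inflammasome, T and NK, B cell, eosinophil and muscle lists the counts adjusted over the list alone were the same. Several of these calls changed when a single library was left out. Stat2 of the interferon list lost its call without air_180 replicates 1, 2, 3, 4 or 6 or MWCNT_180 replicates 2, 4, 5 or 6 (adjusted p from 0.056 to 0.16), and Ifit3 without air_180 replicate 4 or MWCNT_180 replicates 2 or 4 (0.053, 0.098 and 0.092). Thus 2 of the 4 rises could be lost by leaving out any 1 of several libraries. Calls were also lost by Tnnt3 of the muscle list without air_180 replicates 4, 5 or 6 or MWCNT_180 replicates 2, 4 or 6 (0.061 to 0.12), Hdc of the eosinophil and mast cell list without MWCNT_180 replicate 3 (0.089) and Nkg7 of the T and NK list without air_180 replicate 1 (0.061). Calls were gained by Pou2af1 of the B cell list without MWCNT_180 replicate 2 (-0.37, adjusted p = 0.039) and by Tsc22d3 of the glucocorticoid list without air_180 replicates 1 or 2 or MWCNT_180 replicate 4 (0.032, 0.0497 and 0.048). Under other settings Stat2 lost its call with no filter, against all air rats and with the liver trace subtracted (0.085, 0.16 and 0.052), and Tnnt3 with no filter, with set 180 fitted alone and without the 5 libraries with the highest liver trace (0.055, 0.076 and 0.18). Ifit3 and Hdc lost theirs without these 5 libraries (0.13 and 0.070), Hdc with 57 libraries (0.062) and Nkg7 against all air rats (0.12). Pou2af1 was called with limma voom and without the 5 libraries (0.046 and 0.044), Tsc22d3 with DESeq2 and 57 libraries (0.043 and 0.028) and Blk with 57 libraries (0.030).

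The fixed genes that did not pass in set 180 were Ccl24 (0.20 ± 0.19), Arg1 (0.18 ± 0.15), the collagen gene Col1a1 (-0.10 ± 0.09), Sftpc (0.21 ± 0.11) and Cyp1a1 (0.66 ± 0.29, adjusted p = 0.094), and without MWCNT_180 replicate 4 Cyp1a1 passed at 0.82 (adjusted p = 0.039). Against all air rats as a single control Col1a1 passed at -0.34 and Cyp1a1 at 0.90, and with set 180 fitted alone Sftpc passed at 0.21 (adjusted p = 0.0042, 0.0018 and 0.036).

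Camera adjusted p in set 180 was 0.0614 for interferon, 0.128 for inflammasome, 0.474 for T and NK, 0.435 for B cell, 0.361 for eosinophil, 0.563 for fibroblast, 0.145 for glucocorticoid and 0.891 for muscle lists. It was 0.76 for circadian clock genes, of which 5 rose and 4 fell (5 and 5 adjusted over the list alone). No member was called by edgeR in the lists of AhR targets (0 of 6), red blood cells (0 of 8), mesothelium (0 of 7) or thymus and lymph node (0 of 6), where camera adjusted p was 0.792, 0.0883, 0.416 and 0.727. The 4 red blood cell genes followed under other settings, Alas2, Hba1, Hba2 and Hbb, were all called lower with set 180 fitted alone (edgeR, adjusted p from 0.0081 to 0.037), with limma voom (0.0015 to 0.028) and against all air rats as a single control (0.00092 to 0.0084). Without MWCNT_180 replicate 2, Hba2 and Hbb were called (0.046 and 0.049), and so they were without the 5 libraries with the highest liver trace (0.048 and 0.037), as was Alas2 with 57 libraries (0.040). Aldh3a1 of the AhR list was called lower without air_180 replicate 5 (-0.67, adjusted p = 0.041) or 6 (-0.69, adjusted p = 0.028). With limma voom Ccl21 of the thymus and lymph node list passed at -0.31 (adjusted p = 0.026). Median, mean and test direction differed in sign for the B cell, fibroblast, AhR, circadian and glucocorticoid lists, and none of these passed. In all, 19 of 33 lists passed in set 180, 16 up and 3 down, and 10 passed with an estimated correlation.

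**Figure D3:**
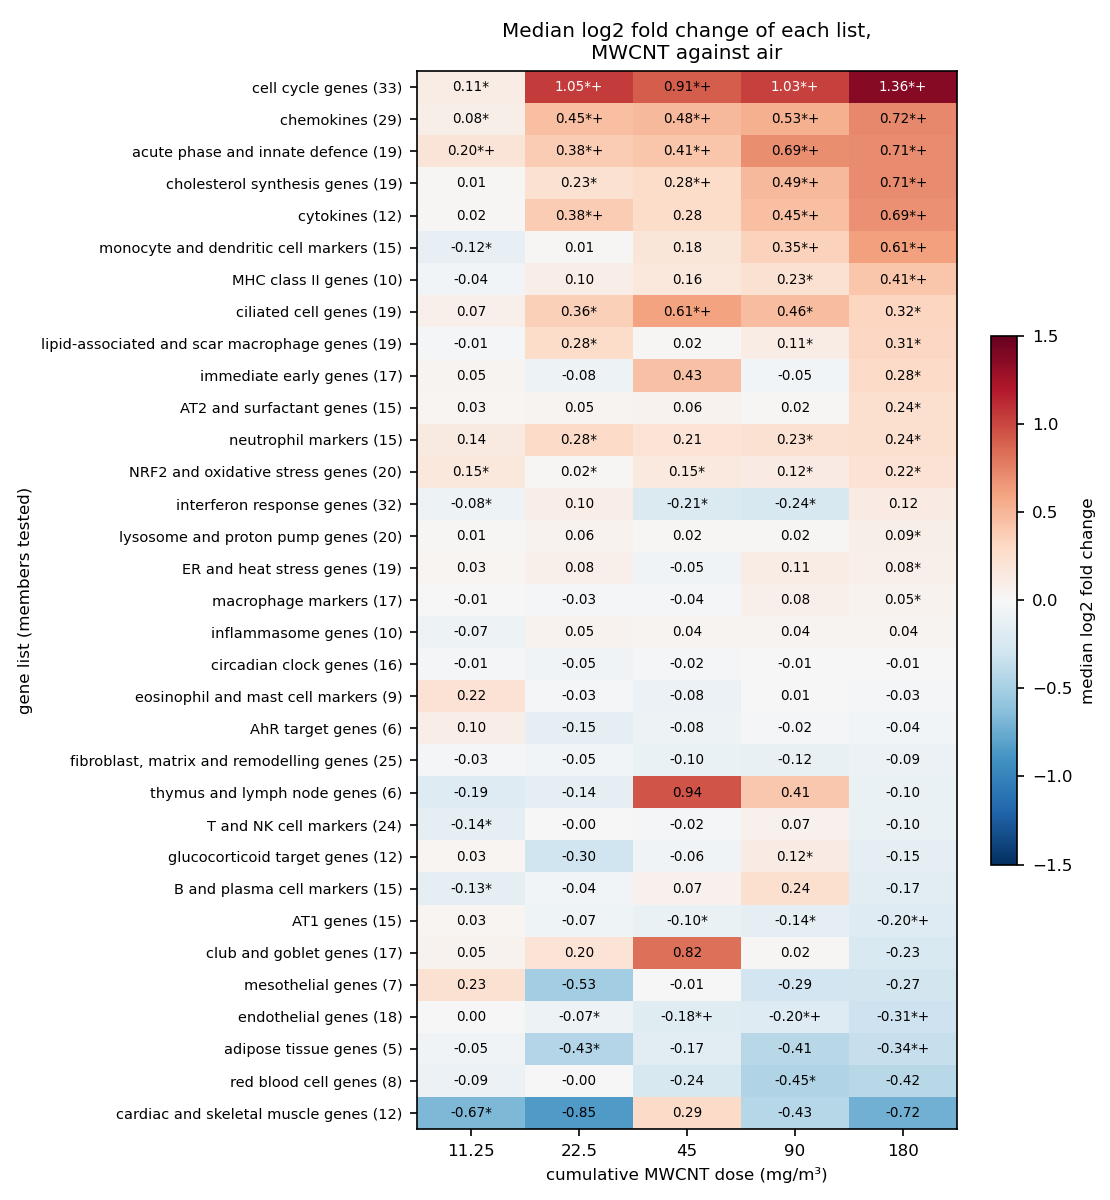
Median log2 fold change (colour and number) of the members tested in each of the 33 gene lists (vertical, number tested in brackets) at each cumulative dose (horizontal, mg/m3). A star marks camera adjusted p under 0.05 and a plus marks the same with an estimated correlation; the cell cycle list has the highest median at 180 mg/m3, 1.36, and stands at 0.11 at 11.25 mg/m3.

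At 90 mg/m3 against its own air group, the largest rises were in the protease Prss30 (log2 fold change 4.05 ± 0.31), Ccno (3.53 ± 0.15), Foxn4 (3.46 ± 0.30), Mcidas (3.42 ± 0.33) and the calcitonin-related peptide gene Calcb (3.41 ± 0.54), each in 4 of 4 exposed rats, as the naming rule required. Ccl2 rose from 4.01 ± 0.53 CPM (SD, n = 6) to 16.7 ± 4.16 (n = 4), and Spp1 from 7.52 ± 4.34 to 69.7 ± 8.7. The largest falls were in Alox15 (-1.40 ± 0.14), Pla2g2d (-1.32 ± 0.14), Cyp2a3 (-2.14 ± 0.71), and the small RNA genes Rmrp (-2.28 ± 0.66) and Mir126 (-1.30 ± 0.41). The falls of Cyp2a3, Rmrp and Mir126 were not called without MWCNT_090 replicate 2 (adjusted p = 0.13, 0.062 and 0.10) or without replicate 4 (0.096, 0.054 and 0.054). Cyp2a3 was also not called without MWCNT_090 replicate 3 (0.12) or air_090 replicates 1, 3, 5 or 6 (0.052 to 0.079), nor Mir126 without MWCNT_090 replicate 1 (0.064) or air_090 replicates 1 or 3 (0.061 and 0.060). Cyp2a3 was not called with no filter (0.060), Rmrp and Mir126 against all air rats as a single control (0.31 and 0.11), and all 3 without the 5 libraries with the highest liver trace (0.10, 0.064 and 0.055).

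Of the cell cycle genes, 31 rose at 90 mg/m3 (32 adjusted over the list alone), with a median of 1.03. So did 17 chemokines (17 up and 1 down adjusted over the list alone), 14 acute phase genes (15), 16 cholesterol synthesis genes (18), and 6 cytokines (7 up and 1 down). Monocyte and dendritic cell markers counted 6 up and 1 down (9 and 1), and 6 endothelial genes fell (13). These lists passed camera with the preset and the estimated correlation, with adjusted p up to 0.019 in the latter. Of the ciliated cell genes, 10 rose (13 up and 1 down adjusted over the list alone), with Foxj1 at 0.85 ± 0.14, and camera adjusted p was 1.74e-10, and adjusted p = 0.104 with an estimated correlation. The interferon list had a median of -0.24 with 2 genes up and 2 down, the same as adjusted over the list alone, and camera adjusted p = 0.00263, and adjusted p = 0.58 with an estimated correlation. Of the 15995 genes, 1775 were called, 1091 up and 684 down, and limma voom called 3226.

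At 45 mg/m3, where the air group kept 3 libraries, the largest rises were in Clca1 (4.05 ± 1.27, adjusted p = 0.049) and Bpifb1 (3.14 ± 0.69), which are goblet cell and airway secretion genes. Ccno (3.37 ± 0.18), the GABA receptor subunit Gabrp (3.20 ± 0.49) and Tmc5 (3.12 ± 0.43) rose too, each in 6 of 6 exposed rats, as the naming rule required. The largest falls were in Amigo2 (-1.07 ± 0.23), Alox15 (-0.98 ± 0.14), the growth factor Bmp2 (-0.94 ± 0.21), Pla2g2d (-0.93 ± 0.15) and Kcnmb2 (-0.91 ± 0.25), each in 6 of 6 by the same rule. Ccl2 rose from 4.77 ± 1.57 CPM (SD, n = 3) to 11.5 ± 2.96 (n = 6), and Spp1 did not pass (1.45 ± 0.47, adjusted p = 0.058). Orm1 had no counts in the air group and 0.92 CPM after exposure, at least 11.3-fold higher by a floor of 3 counts over the group. Clca1 was not called without air_045 replicates 1, 2 or 4 (adjusted p from 0.11 to 0.20) or MWCNT_045 replicates 2, 3, 5 or 6 (0.060 to 0.085), nor Kcnmb2 without air_045 replicates 1, 2 or 4 (0.052, 0.10 and 0.069). Clca1 was also not called with no filter (0.074), with limma voom (0.056) or without the 5 libraries with the highest liver trace (0.058). Those 5 libraries are all from other sets.

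Of the cell cycle genes, 27 rose at 45 mg/m3 (30 adjusted over the list alone), with a median of 0.91. The others were 11 acute phase genes (12 adjusted over the list alone), 10 chemokines (16), 11 ciliated cell genes (14) with a median of 0.61, and 6 cholesterol synthesis genes (12), while 5 endothelial genes fell (9). The acute phase median of 0.41 and the club and goblet median of 0.82 were unchanged with Orm1 and Gp2, which had no counts in air_045, at their bounds. These 6 lists, without club and goblet genes (camera adjusted p = 0.748), were called with the preset and the estimated correlation, with adjusted p up to 0.0433 in the latter. The interferon list had a median of -0.21 with 0 of 32 members called by edgeR or adjusted over the list alone, and camera adjusted p = 0.0017, and adjusted p = 0.723 with an estimated correlation. Of all genes, 865 were called, 531 up and 334 down. The count was 553, 423 and 377 without air_045 replicate 1, 2 or 4, and 1904 with limma voom.

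At 22.5 mg/m3 the largest rises were in Foxn4 (4.21 ± 0.32), Prss30 (3.74 ± 0.30), Ccno (3.67 ± 0.14), Gabrp (2.96 ± 0.37) and Tmc5 (2.89 ± 0.32), each in 6 of 6 exposed rats, as the naming rule required. Ccl2 rose from 3.73 ± 0.722 CPM (SD, n = 6) to 11.8 ± 2.96 (n = 6), and Mki67 from 11.2 ± 1.83 to 24.1 ± 2.63, while Spp1 did not pass (0.80 ± 0.36, adjusted p = 0.20). The largest falls were in Rmrp (-1.83 ± 0.59), the cholesterol transport gene Star (-1.45 ± 0.36), the stress gene Ddit4 (-1.36 ± 0.38), the potassium channel gene Kcna6 (-0.94 ± 0.26) and Klhdc8a (-0.81 ± 0.26). Rmrp lost its call without air_022 replicates 1, 2 or 4 or MWCNT_022 replicates 1, 2, 3, 4 or 6 (adjusted p from 0.055 to 0.19), and Klhdc8a without air_022 replicates 2, 5 or 6 or MWCNT_022 replicates 1, 5 or 6 (0.059 to 0.14). Ddit4 did so without air_022 replicates 1 or 3 or MWCNT_022 replicate 6 (0.051, 0.069 and 0.053), Star without air_022 replicate 4 (0.055) and Kcna6 without MWCNT_022 replicate 6 (0.066). Limma voom did not call Rmrp (-0.87, adjusted p = 0.56), Ddit4 (0.20) or Klhdc8a (0.21), and set 022 fitted alone did not call Ddit4 (0.11), Kcna6 (0.20) or Klhdc8a (0.16). Rmrp and Klhdc8a were not called with no filter (0.071 and 0.062) or without the 5 libraries with the highest liver trace (0.057 and 0.053), which are all from other sets. Nor was Rmrp called against all air rats (0.16) or with 57 libraries (0.096), nor Klhdc8a with DESeq2 (0.0505).

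Of the cell cycle genes, 31 rose at 22.5 mg/m3 (32 adjusted over the list alone), with a median of 1.05 and camera adjusted p = 1.29e-89, and 1.66e-10 with an estimated correlation. Chemokines (13 up, 15 adjusted over the list alone), acute phase genes (11 and 12) and cytokines (4 and 6) also passed both ways, with estimated-correlation adjusted p of 0.007, 2.01e-05 and 0.0497. Of the ciliated cell genes, 9 rose (15 adjusted over the list alone), with camera adjusted p = 2.05e-14, and adjusted p = 0.0631 with an estimated correlation. Cholesterol synthesis genes counted 7 up (10 adjusted over the list alone), with camera adjusted p = 7.33e-06, and adjusted p = 0.231 with an estimated correlation. Of all genes, 1087 were called, 828 up and 259 down. The count was 2919 without air_022 replicate 2, and 341 with set 022 fitted alone. Pairs of libraries within a group differed most in this set. The highest chi-square per degree of freedom was 34.8 in air_022 and 42 in MWCNT_022, against at most 11 in the groups of other sets.

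At the lowest dose, 11.25 mg/m3, 3 named genes rose. Ccno went from 1.69 ± 0.279 CPM (SD, n = 6) to 4.79 ± 0.718 (n = 5), log2 fold change 1.52 ± 0.16 (adjusted p = 3.6e-08). Chia, the acidic chitinase of airway and alveolar cells, went from 139 ± 14 CPM to 276 ± 46.8 (0.99 ± 0.12, adjusted p = 9.1e-07), and Foxn4 rose by 1.79 ± 0.35 (adjusted p = 0.021). Each rose in 5 of 5 exposed rats, which the naming rule required of Ccno and Chia. Foxn4 in this set lies outside the naming rule and was chosen after its values were seen, as 1 of only 4 genes called. It lost its call without air_011 replicates 1, 2, 3 or 5 or MWCNT_011 replicates 1, 3 or 5 (adjusted p from 0.070 to 0.19), and with limma voom, set 011 fitted alone, 57 libraries or without the 5 libraries with the highest liver trace, while Ccno and Chia kept theirs in these fits. The remaining call was a symbol that carries no gene name, and 0 genes fell by edgeR. At an unadjusted p under 0.05 there were 668 of 15995 genes, a share below 0.05 and so no more than chance alone gives. DESeq2 called 4 genes and limma voom 6. The count was 2 without air_011 replicate 1 or 5 or MWCNT_011 replicate 3 or 5, or without the 5 libraries with the highest liver trace, and 263 with all air rats as a single control.

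Of 19 acute phase genes at 11.25 mg/m3, 1 was called (5 adjusted over the list alone), with a median of 0.20 and camera adjusted p = 2.79e-14, and 0.00159 with an estimated correlation. Of 33 cell cycle genes 0 were called by edgeR, and 0 adjusted over the list alone, with a median of 0.11 and camera adjusted p = 0.000957, and adjusted p = 0.52 with an estimated correlation. Muscle genes had the lowest median, -0.67, with 0 of 12 called by either count and camera adjusted p = 3.47e-05, and adjusted p = 0.52 with an estimated correlation. In all, 9 lists passed camera, 4 up and 5 down, and 1 passed with an estimated correlation.

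**Figure D4:**
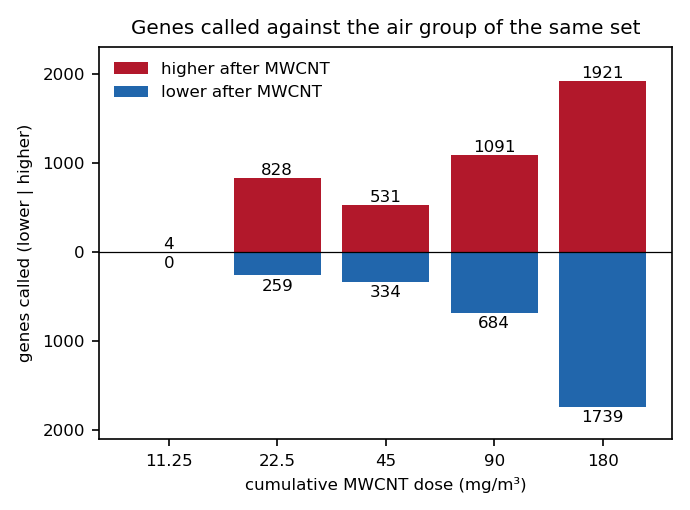
Number of genes called higher (red, above 0) and lower (blue, below 0) after MWCNT than in the air group of the same set (vertical) at each cumulative dose (horizontal, mg/m3). The count goes from 4 at 11.25 mg/m3 to 3660 at 180 mg/m3, with 1087 at 22.5 and 865 at 45 mg/m3.

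The change of the MWCNT effect per doubling of dose asks which genes followed the dose. The steepest rises were in Spp1 (log2 slope 1.20 ± 0.13 SE per doubling), Ccl22 (0.83 ± 0.07), Slc26a4 (0.73 ± 0.09), Ccl7 (0.70 ± 0.12) and Ccl2 (0.66 ± 0.08). The steepest falls were in the selenium-binding protein Selenbp1 (-1.27 ± 0.33), Dlk1 (-0.48 ± 0.10), Serpinb10 (-0.47 ± 0.04), Alox15 (-0.42 ± 0.04) and Cidec (-0.40 ± 0.08). Of 33 cell cycle genes, 28 rose with dose (31 adjusted over the list alone), and so did 19 of 19 cholesterol synthesis genes (19), while 9 endothelial genes fell (11). Camera called 19 lists, 16 up and 3 down, and 9 with an estimated correlation, among them chemokines, acute phase, monocyte, MHC class II, cytokine and AT1 genes. The slope differed from 0 in 1704 genes, 893 up and 811 down. Selenbp1 lost its call without MWCNT_011 replicate 1 (slope -0.52, adjusted p = 0.33), and 244 genes were called without set 011 and 362 without set 180. Without set 180, Dlk1 and Cidec were not called (adjusted p = 0.14 and 0.31), and without set 011, neither were Dlk1 and Selenbp1 (0.16 and 0.096). Selenbp1 was also not called without set 090 (slope -1.06, adjusted p = 0.067) or without the 5 libraries with the highest liver trace (-0.47, adjusted p = 0.49).

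The size of the effect differed between sets most firmly for Cyp4b1, a lung cytochrome P450 of club cells, whose fall went from -0.09 ± 0.05 at 11.25 mg/m3 to -0.98 ± 0.05 at 180 mg/m3 (adjusted p for the difference 9.3e-11). The next genes were Ccl22, from 0.43 ± 0.24 to 3.65 ± 0.20 (9.3e-11), Serpinb10, from -0.08 ± 0.11 to -2.05 ± 0.13 (9.3e-11), Sod2, from 0.18 ± 0.08 to 1.40 ± 0.08 (5.8e-10), and the leukocyte receptor Lilrb4, from -0.08 ± 0.08 to 1.09 ± 0.08 (5.9e-10). In all, 787 genes differed between sets, and 427 without the 5 libraries with the highest liver trace.

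Responses to the 4 higher doses were largely shared in direction. Of the genes called up at 90, 45 and 22.5 mg/m3, 83.5%, 82.5% and 76.3% were also called up at 180 mg/m3, and of those called down, 81%, 71.6% and 79.2%. The shared rises were 911, 438 and 632, against 131, 63.8 and 99.4 for independent calls, and no gene called in set 180 was called the opposite way in another set. Of the genes called at 45 mg/m3, 81.5% of rises and 49.4% of falls were also called at 90 mg/m3. Of those called at 22.5 mg/m3, 47.8% of rises and 29% of falls were also called at 45 mg/m3, and 71.9% and 51.7% at 90 mg/m3. Sets 090 and 045 had 1 gene called in opposite directions, and so had sets 090 and 022. In 1 direction at all of the 4 higher doses were 396 genes, 338 up and 58 down. Of the genes called in set 180, 96.9% changed in the same direction in 090, 91.7% in 045, 91.2% in 022 and 59.7% in 011. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes with set 180 was 0.597 for 090, 0.502 for 045, 0.53 for 022 and 0.0915 for 011.

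The air groups differed from each other too. Between the 5 air groups, 1137 of 15995 genes differed at an adjusted p under the same threshold, although none of these rats had been exposed. Spp1, Ccl2 and Mki67 did not pass in this comparison (adjusted p = 0.22, 0.25 and 0.076). The count was 709, 540, 661 and 757 without air_011 replicate 1, 2, 3 or 4.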

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

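The tests of whether exposure turned on liver genes, of airway tissue behind Ccno, Foxn4 and Mcidas in set 180, and of cell division behind Ccno and Foxn4 in set 011 were chosen only after the results were seen. The list of multiciliogenesis regulators was also written after the largest changes had been seen.

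Liver marker genes exceeded the highest share in an analysed air library, 0.0516% of counts, in 6 of the 7 libraries with an outlier label, which the comparisons did not use. The shares were 24.3% in air_045 replicate 5, 26.2% in MWCNT_090 replicate 5, 27.9% in MWCNT_090 replicate 6, 0.495% in air_045 replicate 6, 0.313% in MWCNT_011 replicate 2 and 0.199% in MWCNT_180 replicate 1. The tables argue against exposure having turned on liver genes, since the air library air_045 replicate 5 held 471 times the share of the highest analysed air library. Whether the 3 highest libraries came from liver alone or from liver with a little lung cannot be told apart. Their median lung marker levels were 0.0289% of the analysed level in air_045 replicate 5, 1.25% in MWCNT_090 replicate 5 and 0.45% in MWCNT_090 replicate 6, and 1.25 missed a bound of 1 set in advance. A small admixture of liver may explain the other 3, but this too stays open, because over 16 markers not looked at before the correlations with the liver profile were 0.937, 0.916 and 0.885 against a preset bound of 0.9, while lung markers stood at 100 to 107%.

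The remaining library with an outlier label, air_045 replicate 3, had 5.19 in units of 1000000 counts and a liver marker share of 0.0291%, and the reason for its label was not tested.

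More genes were called at 22.5 than at 45 mg/m3, 1087 against 865, but the order was reversed with each set fitted alone (341 against 1180), limma voom (1055 against 1904), 57 libraries (877 against 1085) and all 60 (163 against 877). Leaving out MWCNT_022 replicate 6 alone also put set 022, at 735, below 865. Where the larger count at 22.5 mg/m3 holds, the smaller air group of 3 libraries at 45 mg/m3 may account for it: taking 3 of the 6 air_022 libraries in all 20 ways gave a median of 820 genes, from 392 to 2141, and 10 of the 20 counts were at or below 865. These draws do not isolate group size, because they also vary which air_022 libraries are kept. Without air_022 replicate 2 alone, set 022 had 2919 genes. A smaller response at 45 mg/m3 cannot be told apart from an equal one, because the mean signed change over the genes called in set 180 differed by 0.0202 with a standard error of 0.0343. That mean was 0.502 ± 0.0127 in set 180, 0.335 ± 0.0167 in 090, 0.257 ± 0.0285 in 045, 0.237 ± 0.0191 in 022 and 0.0374 ± 0.0167 in 011, and the choice of genes raises the value of set 180. Differences between the exposure runs, and the wider spread between libraries of set 022, stay open and were not tested.

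Genes that start the formation of ciliated cells were among the largest rises, and of 17 multiciliogenesis regulators 8 were called up in set 180, 9 in 090, 7 in 045, 7 in 022 and 2 in 011. More airway tissue in the exposed lung pieces cannot be told apart, because the ciliated cell median differed from that of the 17 regulators by 0.0345 with a standard error of 0.395, and the club and goblet median, -0.232, by -0.515 with a standard error of 0.656. The distances of list medians from single genes decide nothing, because these genes were picked for their rise: the ciliated cell median lay at -2.09 ± 0.312 SE, and the club and goblet median at -2.64 ± 0.609, from the lowest of Ccno, Foxn4 and Mcidas in set 180, and the cell cycle median was 0.108 ± 0.0311 at 11.25 mg/m3, where Ccno (1.52 ± 0.16) and Foxn4 (1.79 ± 0.35, not called with limma voom or without air_011 replicate 1, 2, 3 or 5 or MWCNT_011 replicate 1, 3 or 5) rose. A further test took 5 regulators, Gmnc, Ccdc78, Hes6, Rfx2 and Rfx3, to have no part in cell division, an assumption that was not itself tested. General cell division also remains open, because these 5 had a median of 0.133 in set 180 with 0 of 5 called up by edgeR. At an unadjusted p under 0.05 Gmnc was higher and Rfx2 lower, and Gmnc was called up in set 090 (0.75 ± 0.21, adjusted p = 0.012). An early step of ciliated cell formation thus remains a hypothesis, and cell numbers were not measured.

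Total counts and the levels of single genes were each examined within a group of libraries, and in 15 of these cases, or 10.3%, 1 library lay far from the rest by the 95% critical value of Dixon's ratio of gap to range. By that choice of critical value chance marks about 1 in 20, and many of the cases share the same rats. For total counts, in units of 1000000, these were air_022 replicate 6 (16.2, the highest) and MWCNT_180 replicate 2 (8.1, the lowest). In air_180, the highest were replicate 1 for Ccl7 (2.61 CPM), replicate 3 for Il1b (33.7), replicate 5 for Serpinb10 (37.1), and replicate 6 for Pla2g2d (210), Abcd2 (33.5) and Sftpa1 (8900), and the lowest was replicate 6 for Il33 (404). In MWCNT_180, replicate 5 was the lowest for Ucp3 (2.03) and the highest for Cyp1a1 (8.53). In set 022 the highest were air_022 replicate 6 for Gabrp (5.3) and Tmc5 (4.26), air_022 replicate 4 for Star (10.1) and MWCNT_022 replicate 4 for Ddit4 (47). The reasons were not tested.

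The effect of MWCNT differed between the doses in 787 genes (427 without the 5 libraries with the highest liver trace). It also differed in 30 of 44 named genes examined for it. Besides the fixed group, these 44 held the genes with the smallest p-values for this difference and those with the largest changes at the highest dose. They were picked from the same data, so the share of 30 in 44 is raised by that choice and no conclusion is drawn from it. Adjusted p-values of the difference were 9.3e-11 for Cyp4b1, Ccl22 and Serpinb10, 5.8e-10 for Sod2, 5.9e-10 for Lilrb4, 1.7e-08 for Alox15, 2.1e-08 for Ccno, 3.7e-08 for Mki67, 4.9e-07 for Spp1, and 1.5e-06 for Ccl2 and for Pla2g2d. They were 7e-06 for Slc26a4, 9.9e-06 for Mmp12, 1.4e-05 for Tnn, 3.3e-05 for Abcd2, 4.8e-05 for Prss30, 5e-05 for Saal1, 7.6e-05 for Ucp3, 0.00025 for Retnla and 0.00035 for Ccl7. The others were Cxcl6 (0.0012), Lcn2 (0.0013), Dlk1 (0.0047), Tnfrsf8 (0.0056), Cidec (0.0066), Ccl17 (0.0072), Timp1 (0.02), Foxn4 (0.022), Orm1 (0.035) and Cxcl1 (0.04).

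Shuffling the labels asked whether chance could give as many genes. Labels were shuffled within sets, and for the air groups among all air libraries across sets. With each set's libraries fitted alone, chance can be excluded for set 180 (3319 genes, at most 122 in another of 100 splits), 090 (1999, at most 51 of 100 splits), 045 (1180, at most 2 in all 84 splits) and 022 (341, at most 4 of 100), where only the real split, 1 in each, reached the count. For set 011, 2 of 100 splits, the real one included, called 3 genes or more. The other split called 30, several times the real count, so chance is not excluded for a count of 3. Whether these samples hold a structure was not tested. Chance can be excluded for the air groups fitted alone, 1 of 100 (910 genes, at most 5). For the slope over doses only the real split, 1 of 100, reached the count (1704 genes, at most 1109 in another). For the difference between doses 4 of 100 splits gave as many as 787 genes, with 1095 in the highest other. Shuffling within sets takes the MWCNT effect out of every set. It therefore cannot decide whether an equal effect at all doses would give as many genes. No verdict on chance is drawn from it for the slope or the difference. The draw for the slope and the difference was extended from 30 to 100 splits after its first 30 had been seen, in which 2 of 30 gave as many for the difference, with 884 in the highest other. In an earlier draw of 30 with other random numbers only the real split, 1 of 30, did so. The draws for the sets were extended in the same way from 60 to 100 splits.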

How the results depend on the processing

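The fits of 57 libraries, with the liver trace subtracted, and without the 5 libraries with the highest trace were chosen only after the data had been seen. DESeq2 (5 counts of genes called), its size factors, no filter and a stricter filter (8 counts each) left each count within 1.5 times the value in the report, and so did 57 libraries (8) and subtraction of the trace (8, with the count of gene lists). Without set 022, 045 or 090, and with a linear dose, the slope count also stayed in that range. Of results for named genes and lists, 198 stayed on their side of the threshold with DESeq2's size factors, 196 with the stricter filter, 192 with no filter (6 weaker), 181 with DESeq2 (1 weaker, 1 stronger), 193 with 57 libraries (2 weaker, 3 stronger) and 230 with subtraction of the trace (1 weaker). They were 172 with limma voom (5 weaker, 6 stronger), 167 with sets fitted alone (6 weaker, 5 stronger), 171 with all air rats as a single control (6 weaker, 6 stronger), 185 without the 5 libraries (10 weaker, 3 stronger), 2715 without a single library (64 weaker, 9 stronger), and 45 without a set (5 weaker); with all 60 libraries 78 of 230 were weaker, 2 stronger and 1 reversed.

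All 60 libraries gave 614 genes in set 180, 5122 in 090, 163 in 022 and 0 by edgeR in 011 (139 at an unadjusted p under 0.05, with no other tool run on 60), 99 for the slope and 2415 for the difference between doses. The counts of 877 in set 045 and 820 for the air groups were close to those of 53 libraries, but only 239 genes in set 045 and fewer between the air groups were shared with them, and set 045 turned from 531 up and 334 down to 230 up and 647 down. The slope of Cidec reversed to 0.316 (adjusted p = 0.78), against -0.45 (without set 011) to -0.24 (without set 180) in its other fits. Leaving out the 3 liver-profile libraries gave 3828, 1501, 877, 3, 1809 and 1050 for the first 6 counts, so the 3 libraries account for the change. Limma voom called 3226 genes in set 090 and 1904 in 045, and set 022 fitted alone called 341. All air rats as a single control gave 2689 in set 045, 3516 in 022 and 263 in 011; this control mixes sets, and 1137 genes differed between air groups. The slope was called in 362 genes without set 180 and 244 without set 011. Those fits hold fewer rats and span a shorter range of doses, which were not separated. Fits without set 022, 045 or 090 also hold fewer rats, and their slope counts stayed within the range given above. Without the 5 libraries with the highest trace, 2 genes were called in set 011 and 427 for the difference, and the estimated correlation left 10 of 19 lists in set 180. Removal of these libraries also leaves fewer rats in sets 180, 090 and 011, which was not separated from the trace. Except where stated, the cause was not tested.

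Leaving out 1 library at a time gave 3182 to 3647 genes in set 180, 1314 to 1743 in 090, 1455 to 1980 for the slope and 657 to 1051 for the difference between doses. Set 045 ran from 377 without air_045 replicate 4 to 811 without MWCNT_045 replicate 1, with 553 and 423 without air_045 replicates 1 and 2. Set 022 ran from 735 without MWCNT_022 replicate 6 to 2919 without air_022 replicate 2. Set 011 ran from 2, without air_011 replicate 1 or 5 or MWCNT_011 replicate 3 or 5, to 5 without MWCNT_011 replicate 6. The air groups ran from 540 without air_011 replicate 2 to 1440 without air_022 replicate 6, with 709, 661 and 757 without air_011 replicates 1, 3 and 4. Small changes were missed in part: on simulated data 47.5% of 1.5-fold rises were called in set 045, with 3 air libraries, and 70% in set 180. Of 1.5-fold falls, 77.5% were called in set 045 and 82.5% in set 180. Depth was not varied in the simulation.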

Other observations

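The examination of clock genes was chosen only after the results were seen, although the list was written before.

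Clock genes shifted in opposite directions in set 180. The activators Npas2 (-0.62 ± 0.08, adjusted p = 9.8e-08) and Arntl (-0.57 ± 0.10, adjusted p = 6.7e-06) fell, as did Cry1 (-0.59 ± 0.18, adjusted p = 0.011) and Ciart (-0.38 ± 0.11, adjusted p = 0.010). Nr1d1 (1.69 ± 0.47), Dbp (1.39 ± 0.31), Per3 (0.81 ± 0.23), Nr1d2 (0.75 ± 0.19) and Bhlhe40 (0.42 ± 0.09) rose. Npas2 and Arntl were also called lower at 90 mg/m3 (-0.29 and -0.33) and 22.5 mg/m3 (-0.29 and -0.28), and Cry1 at 45 mg/m3 (-0.75). The list as a whole did not pass camera in any set. The time of day at which each rat was killed is not given, so exposure and hour of sampling were not separated.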
